A study of Homo sapiens with 36 samples.

How the data were processed

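The series holds 36 arrays with 54675 probe sets each, from 18 pancreatic tumours in duplicate. Per the labels, total RNA was extracted with Trizol and biotin-labelled cRNA was hybridised; the labels call the material tumour and do not say whether it was taken directly from patients or grown in animals. Per the submitters' processing notes, the authors computed the deposited signal intensity of each probe set with MAS5 (version not given), and the values are on a linear scale. The mean of each array without the lowest and highest 2% of probe sets was 100 in 30 arrays and 150 in 6 arrays, so the authors scaled the arrays to 2 targets. The 6 arrays belong to 1 sensitive and 2 resistant tumours. The scanner and the normalization text are not given in the sources used here. The number of arrays, 2 for each of the 18 tumours, and of tumours limits the precision.

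All arrays were rescaled to a target of 100, and values were transformed as log2(signal + 16). Rescaling did not make the arrays alike at low signal. The median signal per array was then 32.1 (range 25.6 to 38.8) in the 6 arrays of the higher target. In the other 30 arrays it was 21.3 (16.6 to 36.8). The choice of the gene filter, the gene lists, the tests and the naming rule was made before the data were examined, with arrays used as deposited. Rescaling to 1 target was chosen after the 2 targets were seen in the values, because the higher target holds 1 of 3 sensitive tumours, and values as deposited were then kept as an alternative. As deposited, 17 genes passed in all tumours and 6 in training, 9 gene lists passed, and the EGFR pathway score differed by 0.13 (exact permutation p = 0.348, two-sided). As deposited, 6842 genes of the sensitive validation tumour lay outside the range of the resistant ones, most of them above it, with a median shift of 0.50 over all genes, and the score on the training genes had a difference of 1.29.

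The 2 arrays of a tumour were averaged on the log2 scale, so 1 tumour was 1 replicate. Of the probe sets, 62 were controls, 41091 had 1 gene symbol, 1801 had several and 11721 had none. Probe sets with 1 symbol were kept, and 41037 of these symbols were brought up to date through a gene table of assembly GRCh38.p14, which was used for names and neighbouring genes only. The 97 probe sets of XIST, its neighbours and Y-linked genes were left out. For each of 19739 genes the probe set with the highest mean over the 18 tumours was used. A gene was tested if its value was above 5.31, the median of all probe sets, in at least 3 tumours, which left 15575 genes. Signal near the floor of 4 set by the added 16 is hardly distinguishable from background.

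Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Comparisons were sensitive against resistant in all tumours and in training tumours, training against validation and higher against lower scaling target in resistant tumours, and the interaction of response and set. Of 33 gene lists written from textbook knowledge, 32 had at least 5 tested genes and were tested with camera (preset correlation 0.01), with camera at an estimated correlation and with fry. List scores are means of centred log2 values, compared by exact permutation over every way to choose 3 of 18 tumours. The training genes were ranked by moderated t, and the 50 highest and 50 lowest gave each validation tumour a score. Coordination was the mean pairwise Spearman correlation against 10000 random lists matched on mean expression.

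Genes are named by a fixed rule: among genes past the threshold with all sensitive tumours on the same side of the resistant median, the 12 with the largest rise and the 12 with the largest fall, filled to 12 by the smallest unadjusted p where fewer passed, and likewise 5 each way in training. Every measured EGFR family member was named, and for each list described, the members past the threshold (at most 4) or else the 2 with the smallest p. Genes named outside the rule are marked as chosen after their values were seen, or passed adjusted over a described list alone.

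Alternatives were pseudocounts of 4 and 64, no filter, a filter at 9 tumours, quantile normalization, a common median, the mean of all probe sets, every probe set on its own, either array of a tumour alone, no variance trend, robust eBayes, the set as a covariate, 20 or 200 ranked genes, Pearson in place of Spearman correlation, all arrays with the tumour as a random block (statmod 1.5.0), and each tumour left out in turn. Added after the data were seen were the scaling as deposited, the target as a covariate, leaving out the higher target, the actin ratio as a covariate, and counting the 2 most similar resistant tumours as 1. The steps were tested on simulated data with 15575 genes. For 3 against 15 tumours they recovered 22%, 80%, 96% and 98% of genes changed by 1, 2, 3 and 4 on the log2 scale, and for 2 against 8 tumours 4%, 24%, 84% and 98%. Of the genes called there, 11 of 159 and 5 of 110 were unchanged genes. The simulated noise was normal, independent between genes and of the same spread in both groups. It held no correlated genes or outlying tumours, so these rates need not hold for the real arrays.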

Results

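Transcript levels were measured in 18 pancreatic tumours on 36 expression arrays, with 2 duplicate arrays per tumour. The labels call 3 tumours sensitive and 15 resistant to inhibition of EGFR, the epidermal growth factor receptor, a kinase at the cell surface that drives RAS-MAPK and PI3K-AKT signalling. The study split the tumours into a training set of 2 sensitive and 8 resistant tumours and a validation set of 1 sensitive and 7 resistant tumours. Tumours are numbered here within each response group. The median Pearson correlation across genes was 0.955 between the duplicate arrays of a tumour (18 pairs) and 0.828 between arrays of different tumours (612 pairs); genes are not independent replicates, so no p is given. Of the 36 arrays, 31 were most similar to the other array of their own tumour and 5 to an array of another tumour. The ratio of 3' to 5' beta-actin signal, a measure of RNA degradation, averaged 2.84 ± 1.43 (SD, n = 3) in sensitive and 2.92 ± 2.76 (SD, n = 15) in resistant tumours as arithmetic means. Its highest value was 12.2, in resistant tumour 4. On the log2 scale, where the ratio was tested, sensitive tumours were higher by 0.17 (exact permutation p = 0.772, two-sided). All log2 values are means of the duplicate arrays, and the number of tumours limits their precision.

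The first comparison asked which genes separated sensitive from resistant tumours. CPE, which encodes the prohormone-processing enzyme carboxypeptidase E, rose by 3.23 ± 0.39 (SE) on the log2 scale, from 4.86 ± 0.65 (SD, n = 15) in resistant to 8.09 ± 0.52 (SD, n = 3) in sensitive tumours (limma adjusted p = 0.000463). BMP4, a secreted ligand of the TGF-beta superfamily, fell by 3.16 ± 0.39, from 8.01 ± 0.64 in resistant to 4.85 ± 0.44 in sensitive tumours (adjusted p = 0.000463). CDKN2B, an inhibitor of the cell-cycle kinases CDK4 and CDK6, rose by 2.60 ± 0.37, from 4.56 ± 0.62 to 7.16 ± 0.60 (adjusted p = 0.00309). SERPINB3, a protease inhibitor of the serpin family in squamous epithelium, had the largest rise among the passing genes, 4.07 ± 0.73 (adjusted p = 0.0241). Its SD was 3.20 in sensitive and 0.66 in resistant tumours, while the fit assumes 1 spread for both groups. SERPINB3 was measured by a probe set of the class that shares sequence with related genes such as SERPINB4.

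EPHB1, a receptor tyrosine kinase for ephrins, rose by 2.94 ± 0.48 (adjusted p = 0.00915), and NDP, which encodes the FZD4 ligand norrin, rose by 2.29 ± 0.35 (adjusted p = 0.00497). CLTRN, a transmembrane glycoprotein gene, rose by 2.93, and PPP2R2C, a regulatory subunit of protein phosphatase 2A, by 2.58. ABCC4, an exporter of nucleotides and drugs, rose by 2.17, LRP12 by 1.77 and TMEM273 by 2.11. NFE4 rose by 3.22 and the long non-coding RNA LINC01503 by 2.38. For these 7 genes the limma adjusted p lay between 0.00465 and 0.0471. The SD in sensitive and resistant tumours was 2.75 and 0.53 for NFE4, and 2.12 and 0.29 for LINC01503. HOMER2, outside the naming rule and chosen after its values were seen, rose by 1.71 (adjusted p = 0.0475) and completes the 14 of 15575 tested genes that passed, 13 higher and 1 lower in sensitive tumours, against 1069 genes at an unadjusted p under 0.05. The 3 sensitive tumours did not overlap the 15 resistant tumours in 45 genes, 0.289% of those tested where chance gives 0.245%. CPE, CDKN2B, EPHB1, NFE4, LINC01503, TMEM273 and LRP12 had resistant means, and BMP4 a sensitive mean, within 1 of the floor of 4, where a difference depends on the value added before the logarithm. Over the alternatives and leave-outs CPE ranged from 2.11 to 4.06, CDKN2B from 1.40 to 3.71, EPHB1 from 0.80 to 3.44, NFE4 from 2.25 to 4.88, LINC01503 from 1.42 to 3.58, LRP12 from 0.92 to 2.48 and TMEM273 from 0.23 to 2.88. The lowest values of TMEM273 and EPHB1 came from arrays numbered 1 alone (limma adjusted p = 0.973 and 0.869). In that setting the probe set of each gene was chosen anew from those arrays. These 2 values therefore do not tell a change of probe set from a disagreement of the duplicate arrays. The other passing genes with ranges were SERPINB3 from 2.79 to 5.95, CLTRN from 2.01 to 3.74, PPP2R2C from 0.79 to 3.09, ABCC4 from 0.93 to 2.82, NDP from 1.39 to 2.89 and BMP4 from -4.03 to -1.98.

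**Figure D1:**
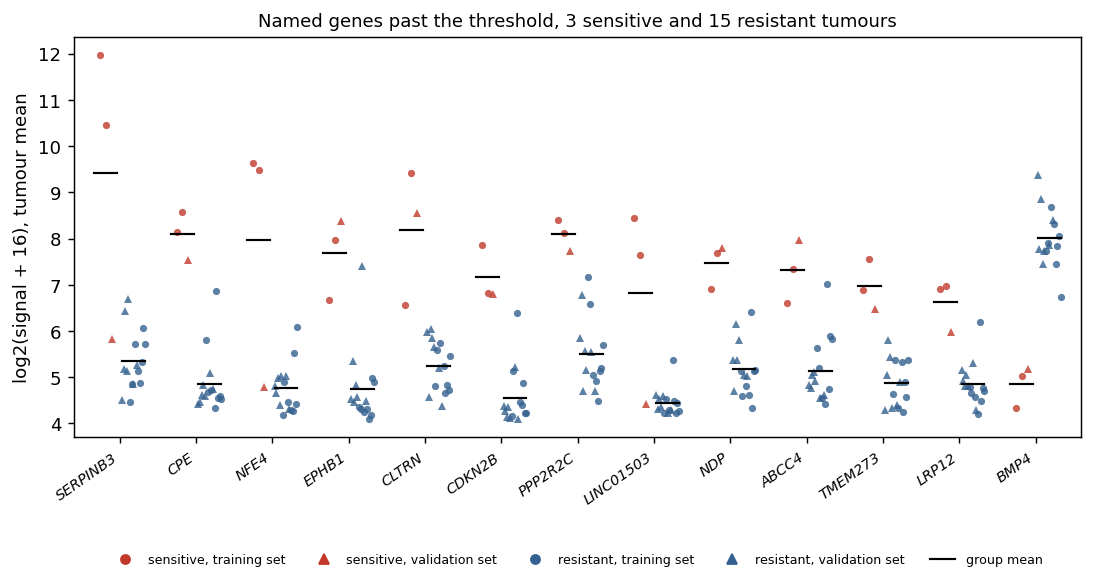
Log2(signal + 16) per tumour, as the mean of 2 arrays, for the 13 named genes that passed the threshold; points are tumours, circles the training set, triangles the validation set, and bars group means (3 sensitive in red, 15 resistant in blue). CPE and CDKN2B were higher and BMP4 lower in all 3 sensitive tumours than in every resistant tumour, while the sensitive tumour of the validation set lay within the resistant range for SERPINB3, NFE4, LINC01503 and LRP12.

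Among genes lower in sensitive tumours, BMP4 alone passed. REG4, a secreted lectin of intestinal-type epithelium, had 5.76 ± 0.77 in sensitive and 12.3 ± 2.89 in resistant tumours, a difference of -6.56 ± 1.50 that did not pass (adjusted p = 0.125). IRF8, a transcription factor, and PLAC8 differed by -2.49 and -3.22, and the thyroid hormone receptor gene THRA by -1.29, each with an adjusted p of 0.125. TNK2 (-1.91), ICA1 (-1.87) and CREB3L1 (-1.60) had the same adjusted p, and IRS2, CPLX1, NR1H3 and ALDOC had adjusted p from 0.206 to 0.222. Without resistant tumour 12 the count of passing genes was 53, with REG4 (adjusted p = 0.00283) and IRF8 (0.00329) among them, as were TNK2 and ICA1. The count was 8 without sensitive tumour 2, 29 without sensitive tumour 1 and 30 without sensitive tumour 3; PLAC8 passed without sensitive tumour 1 (adjusted p = 0.0236) and differed by -2.09 without sensitive tumour 3 (adjusted p = 0.569).

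CPE, BMP4 and CDKN2B passed whichever of the 18 tumours was left out. SERPINB3 missed the threshold without sensitive tumour 1 (adjusted p = 0.166) or sensitive tumour 2 (0.187), PPP2R2C likewise (0.0860 and 0.109), and LRP12 likewise (0.0895 and 0.172). CLTRN (0.0752), NDP (0.0661) and TMEM273 (0.0752) missed it without sensitive tumour 2, and EPHB1 without sensitive tumour 2 (0.0849) or sensitive tumour 3 (0.0688). NFE4 and LINC01503 each missed it in 15 of the 18 leave-outs and ABCC4 in 14, with adjusted p up to 0.287, 0.280 and 0.217. The arrays carry 2 scaling targets, with sensitive tumour 3 and resistant tumours 14 and 15 at the higher one. All 14 genes passed with the target as a covariate (16 genes in all), and 9 of them passed within the 2 sensitive and 13 resistant tumours of the lower target (18 genes in all).

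The title of the series names the EGFR pathway, so its members were examined next; the pathway was named by the study on these samples, and its counts are not independent evidence. EGFR had 8.63 ± 1.44 (SD, n = 3) in sensitive and 7.88 ± 0.68 (SD, n = 15) in resistant tumours, a difference of 0.75 ± 0.49 (SE) that did not pass (limma adjusted p = 0.827). Of the 5 EGFR probe sets with a mean above 5.31, the median of all probe sets, 3 were higher and 2 lower in sensitive tumours. EREG, which encodes the EGFR ligand epiregulin, differed by 2.06 ± 0.66 (adjusted p = 0.407), and the ligand HBEGF by 1.02 ± 0.46 (adjusted p = 0.694). TGFA differed by 0.59 and EGF by 0.72, while the related receptors ERBB2 and ERBB3 differed by -0.89 and -0.59. ERBB4 (0.15), NRG1 (-0.15), NRG2 (0.31) and BTC (0.14) had the smallest differences of the family. Without sensitive tumour 1, EGFR differed by -0.083, ERBB3 by 0.20 and BTC by -0.046; without sensitive tumour 2, EGF differed by -0.11, and without sensitive tumour 3, ERBB4 by -0.086. EREG differed by 1.18, HBEGF by 0.49 and ERBB2 by -0.52 without sensitive tumour 1. TGFA ranged from 0.21 without sensitive tumour 2 to 1.17 without sensitive tumour 3. Of its 3 probe sets with a mean above 5.31, 2 were higher and 1 lower in sensitive tumours. Of the 11 measured family members, 0 passed limma over all genes and 0 adjusted over the list alone, and 2, EREG and HBEGF, had an unadjusted p under 0.05. The list held 14 genes, and AREG, EPGN and NRG4 were not among the tested ones. EGF, ERBB4, NRG1 and NRG2 had 0 probe sets with a mean above 5.31, so their differences lie near background. The mean score of the family differed by 0.37 between the groups (exact permutation p = 0.0515, two-sided; camera adjusted p = 0.106). Within the tumours of the lower scaling target the family list passed camera as higher (adjusted p = 0.0429), and with the target as a covariate it did not (0.189). In all tumours its adjusted p was 0.353 with an estimated correlation and 0.453 with fry.

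The EGFR pathway list joined 4 arms: the receptors and ligands, the adaptors with the RAS-MAPK cascade, the PI3K-AKT-MTOR arm, and the STAT and PLC-PKC arm. Of its 62 measured genes, 25 were higher and 37 lower in sensitive tumours, 0 passed limma over all genes and 0 adjusted over the list alone, and 4 had an unadjusted p under 0.05. Those were EREG, HBEGF, the PI3K regulatory subunit PIK3R3 (1.18, or 0.74 without sensitive tumour 1) and the cyclin-dependent kinase inhibitor CDKN1B (-0.96). The pathway score differed by 0.027 between the groups (exact permutation p = 0.692, two-sided), with 0.24, -0.00294 and -0.17 in sensitive tumours 1, 2 and 3. Its median change was -0.047 and its mean change 0.027, and camera gave the direction as down (adjusted p = 0.998). Without sensitive tumour 1 the score difference was -0.084. Within the validation set the sensitive tumour had the lowest score, rank 8 of 8. The score of the STAT and PLC-PKC arm differed by -0.27 (exact permutation p = 0.0159, two-sided, adjusted p = 0.209 over 32 lists), with JAK2 at -0.79 (-0.50 without sensitive tumour 2, -1.21 without sensitive tumour 1) and PLCG2 at -1.03; its camera adjusted p was 0.0860. The adaptor and RAS-MAPK arm and the PI3K-AKT-MTOR arm had exact permutation p of 0.544 and 0.888, two-sided. In these 3 arms 0 genes passed in either count, with 0, 0 and 2 at an unadjusted p under 0.05.

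**Figure D2:**
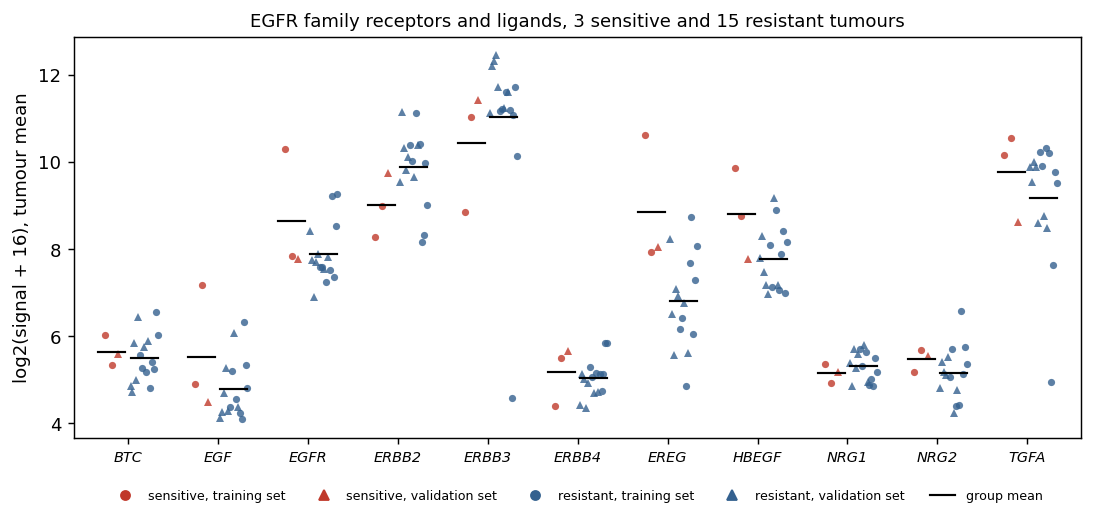
Log2(signal + 16) per tumour, as the mean of 2 arrays, for the 11 measured EGFR family receptors and ligands; points are tumours, circles the training set, triangles the validation set, and bars group means (3 sensitive in red, 15 resistant in blue). The groups overlap in each gene, and EREG has the widest gap between group means, 8.85 against 6.79.

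Targets and brakes of the pathway were tested as separate lists. FOS, an immediate early transcription factor induced by ERK, differed by -1.68 ± 0.54 (adjusted p = 0.409) and SPRY4, a feedback inhibitor, by -0.76. The ERK output and feedback list had 9 of 22 genes higher and a camera adjusted p of 0.166; 0 genes passed limma over all genes, 0 adjusted over the list alone, and 1, FOS, had an unadjusted p under 0.05. For the list of EGFR attenuators and trafficking genes the camera adjusted p was 0.806 and 0 of 23 genes passed or had an unadjusted p under 0.05, with GRB7 at -0.65 and EPS8 at -0.58 (0.20 without sensitive tumour 1).

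Members of the pathway were also compared with each other across tumours, since the title speaks of coordinated expression. Over the 15 resistant tumours, the mean pairwise Spearman correlation of the 62 EGFR pathway genes was -0.00142, at percentile 19.7 of 10000 random lists matched on expression level (median 0.00522). Over all 18 tumours it was 0.00379, at percentile 48.3. For the coordination of EGFR pathway genes in resistant tumours, the values as deposited gave 0.0827, at percentile 96.4, and quantile normalization -0.00538, at percentile 5.55, so the percentile depends on the scaling. These are descriptions without a test.

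Other gene lists were compared between sensitive and resistant tumours to ask which programmes differed. The classical pancreatic tumour list, genes of differentiated gut-like epithelium, was lower in sensitive tumours: 28 of 30 genes had lower values, among them REG4, the cadherin CDH17 (-3.85 ± 1.03), the protease CTSE (-4.04) and the transcriptional regulator TOX3 (-2.01). These 4 passed adjusted over the list alone and 0 passed limma over all genes, with 10 at an unadjusted p under 0.05. Its camera adjusted p of 1.22e-10 was not kept with an estimated correlation between genes (adjusted p = 0.353 with an estimated correlation). Without resistant tumour 12 that p was 0.0499, and CDH17 (adjusted p = 0.00283), CTSE (0.00471) and REG4 passed over all genes. The NF-kB and inflammatory chemokine list was higher in 15 of 19 genes, led by the neutrophil chemokines CXCL6 (4.62 ± 0.97) and CXCL8 (2.91 ± 0.75), with camera adjusted p = 1.59e-06 and adjusted p = 0.277 with an estimated correlation. CXCL6, CXCL8, CCL20, IL1A and SOD2, 5 genes, passed adjusted over the list alone and 0 passed limma over all genes, with CXCL6 at 0.0885 and 7 at an unadjusted p under 0.05. CXCL6 passed in the leave-outs of resistant tumours 11 and 12 and of sensitive tumour 3 (0.00670, 0.0355 and 0.0418) and differed by 3.08 without sensitive tumour 2. The NF-kB list itself did not pass without sensitive tumour 2 (adjusted p = 0.218). Its score was 0.62, 2.46 and -0.083 in sensitive tumours 1, 2 and 3, against -0.20 ± 0.49 (SD, n = 15) in resistant tumours. The mean change of its genes was 1.74 in training and 0.12 in validation.

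TGF-beta target genes were higher in 10 of 11 members, with INHBA (2.23 ± 0.61), a subunit of activin, the 1 gene past the threshold adjusted over the list alone and 0 in limma over all genes. TGFB2 was at 1.28 (1.96 without sensitive tumour 2), and these 2 had an unadjusted p under 0.05; INHBA passed over all genes without sensitive tumour 3 (adjusted p = 0.0326) and differed by 1.03 without sensitive tumour 1 (adjusted p = 0.791). The camera adjusted p was 0.00230 (adjusted p = 0.277 with an estimated correlation), and the 3 sensitive tumours scored 0.97, 0.97 and 0.79 against -0.18 ± 0.67 (SD, n = 15). The basal-like list was higher in 17 of 20 genes (camera adjusted p = 0.00355; adjusted p = 0.531 with an estimated correlation), and SERPINB3 was the 1 member past the threshold both over all genes and adjusted over the list alone. Its score was 3.19 in sensitive tumour 1, -0.68 in sensitive tumour 2 and -0.25 in sensitive tumour 3, and without sensitive tumour 1 the list pointed down (adjusted p = 0.301). Cholesterol and fatty acid synthesis genes were lower in 10 of 12 members, among them DHCR7 (-0.89) and INSIG1 (-1.52, or -0.86 without sensitive tumour 1), which are the 2 with an unadjusted p under 0.05; 0 passed limma over all genes and 0 adjusted over the list alone. The camera adjusted p of this list was 0.00511 (adjusted p = 0.353 with an estimated correlation), or 0.422 without sensitive tumour 1. Ribosomal protein genes were lower in 17 of 18 members by a median of -0.27 (camera adjusted p = 0.0380; adjusted p = 0.806 with an estimated correlation), 0 passed limma over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. The list Ribosomal proteins missed the threshold in 9 of 18 leave-outs, with quantile normalization (adjusted p = 0.729) with a common median (0.0814), with arrays numbered 1 (0.0960), with the actin ratio as a covariate (0.0549), with the 2 most similar resistant tumours counted as 1 (0.0512) and with the scaling target as a covariate (0.485).

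In all, 6 of 32 lists passed camera with its preset correlation, 3 higher and 3 lower. With an estimated correlation 0 passed (3 at an unadjusted p under 0.05), and with fry 0 passed (4 at an unadjusted p under 0.05; lowest adjusted p = 0.170). In fry's mixed test, which asks for change in either direction, the NF-kB list passed (adjusted p = 0.0117). The other 26 lists had camera adjusted p of 0.0536 or more. NRF2 target genes (0.0536) held AKR1C2 (3.08 ± 0.67) and AKR1C1 (2.85 ± 0.67; 1.90 without sensitive tumour 2), aldo-keto reductases of near-identical sequence that the probe sets were not tested to tell apart, and both passed adjusted over the list alone but not over all genes. The NRF2 list passed with the target as a covariate (camera adjusted p = 0.0183), within the lower target (0.000691) and in training (0.00121), but not in training with an estimated correlation (0.471). Its score was 2.20 in sensitive tumour 2, against -0.47 and -0.46 in sensitive tumours 1 and 3. The mesenchymal list (0.156) held fibronectin, FN1 (3.17 ± 1.10), and moesin, MSN (3.06 ± 1.08); FN1 differed by 1.85 without sensitive tumour 2 and 4.82 without sensitive tumour 1. Fibroblast and stellate markers (0.0940; adjusted p = 0.531 with an estimated correlation) were higher in 13 of 19 genes, among them PDGFRA (1.52 ± 0.46) and POSTN (0.78), the 2 with an unadjusted p under 0.05. Of these markers 0 passed limma over all genes and 0 adjusted over the list alone, and the list passed camera within the lower target (0.0493). The proliferation list (0.655) held MCM5 (-0.58) and AURKB (-0.48), and epithelial junction genes (0.0818) held CLDN4 (-1.20) and KRT8 (-0.99). In the mesenchymal, proliferation and epithelial lists 0 genes passed limma over all genes and 0 adjusted over the list alone, with 2, 0 and 1 at an unadjusted p under 0.05. Without resistant tumour 12 the epithelial list and the mucin list passed camera as lower (adjusted p = 0.00153 and 0.00158), but not with an estimated correlation (0.204 and 0.161).

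**Figure D3:**
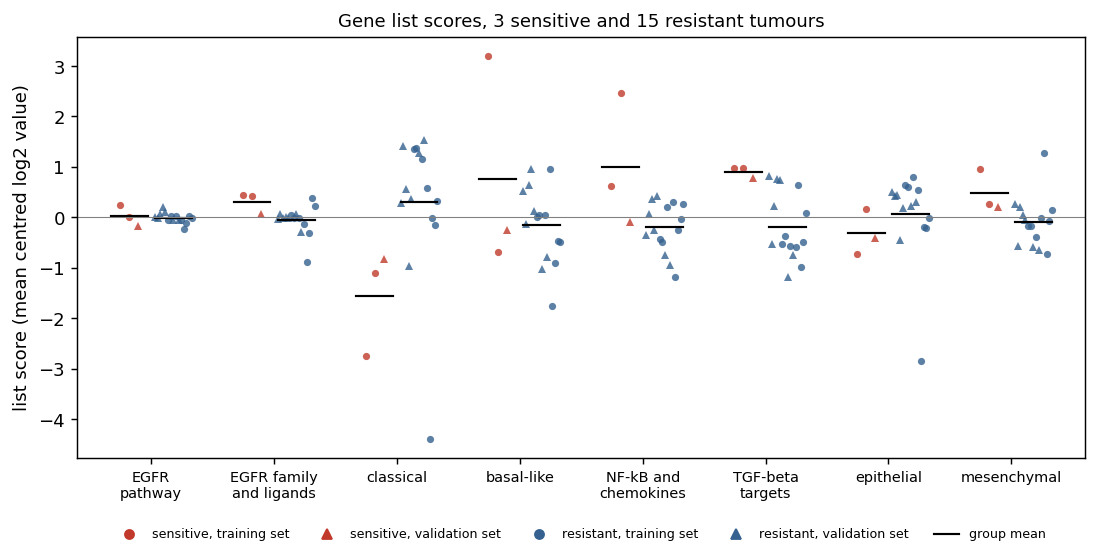
Score per tumour, the mean log2 value of a list's genes centred on the mean of the 18 tumours, for 8 gene lists; points are tumours, circles the training set, triangles the validation set, and bars group means (3 sensitive in red, 15 resistant in blue). The classical score of resistant tumour 12 was -4.39, below all 3 sensitive tumours, and the basal-like mean of the sensitive tumours rests on a score of 3.19 in 1 of them.

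The training tumours were then fitted alone, and the sensitive validation tumour was set against its own set. In training, SERPINB3 rose by 5.94 ± 0.49 (adjusted p = 0.000315), NFE4 by 4.79 ± 0.49 (0.00116), LINC01503 by 3.55 ± 0.35 (0.00116) and FST, which encodes the activin and BMP antagonist follistatin, by 3.72 ± 0.40 (0.00197). RARRES1 rose by 5.67 ± 0.90 (0.0472) and BMP4 fell by 3.16 ± 0.47 (0.0309). In the validation set the sensitive tumour differed from the mean of the 7 resistant tumours by 0.38 for SERPINB3, 0.053 for NFE4, 0.0094 for LINC01503, 0.21 for FST, -1.17 for RARRES1 and -3.03 for BMP4. DPYSL2, PNMA2, ATP2A3 and AFAP1-AS1 were lower in sensitive training tumours without passing, with DPYSL2 at -3.18 ± 0.58 (0.107). Of 15575 genes, 9 passed in training, 8 higher and 1 lower, against 711 at an unadjusted p under 0.05. The validation difference had the same sign for 7 of the 9, and for 2, BMP4 and EPHB1 (2.90 in training, 3.29 in validation), it lay outside the resistant range in that direction. Both fits called 5 genes. The training count was 5 without resistant tumour 6 or 14, 32 without sensitive tumour 2, 45 without resistant tumour 12 and 67 without sensitive tumour 1; RARRES1 missed the threshold in 8 and BMP4 in 7 of the 10 leave-outs, and DPYSL2 passed in 2. DPYSL2 differed by -1.68 without sensitive tumour 1 and -4.69 without sensitive tumour 2. In these 2 leave-outs 1 sensitive tumour remains, so the spread comes from the resistant tumours alone and the sensitive tumour is assumed to vary like them.

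Across all genes, the sensitive validation tumour lay outside the range of its 7 resistant tumours in 31.3% (4874), where chance gives 25%, 2480 above and 2394 below. The sensitive validation tumour had a score of 1.32 on the 50 highest and 50 lowest training genes, against -0.188 ± 0.470 (SD, n = 7) and a highest value of 0.394 in the resistant tumours. It ranked 1 of 8 (exact permutation p = 0.125, one-sided, the smallest this design allows). It is also the 1 validation tumour at the higher scaling target. Its median signal after rescaling was 28.8, within the 20.3 to 33.5 of the resistant validation tumours. A ranking from the training tumours at the lower target gave the sensitive validation tumour 0.370 against -0.163 and -0.207 in the 2 resistant tumours at the higher target, rank 1 of 3 (exact permutation p = 0.333, one-sided, the smallest possible).

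Whether the response difference depended on the set was tested as an interaction, with 6 genes past the threshold and 950 at an unadjusted p under 0.05. SERPINB3, NFE4 and LINC01503 had larger differences in training, by 5.56, 4.74 and 3.54 (adjusted p = 0.0185, 0.00622 and 0.00622). CTNNA1, LDOC1 and DACT2 are the remaining genes, chosen after their values were seen. The cell-adhesion gene CTNNA1 differed by 0.14 in training and -5.14 in validation, LDOC1 by -0.42 and 3.86, and the WNT regulator DACT2 by -0.83 and 3.32. With 1 sensitive tumour in validation, its spread is assumed to equal that of the other groups. Among resistant tumours alone, limma found 0 genes that differed between the sets, with 791 at an unadjusted p under 0.05, and 510 genes, 285 higher and 225 lower, that differed between the 2 tumours at the higher and the 13 at the lower scaling target.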

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

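The tests of the scaling targets and of resistant tumour 12 were chosen only after the results they address had been seen. The estimated correlation between genes was planned as an alternative, and its use as a test of an explanation was chosen after its result was seen. The actin test was added after the data were seen but before its own result, and the other splits of the tumours were planned. Single tumours stood apart from the other resistant tumours of their own set, training or validation, by the gap to the nearest other tumour, in 12 of 99 groups tested, where chance gives about 1 in 20 groups, or 4.95. EPHB1 was 7.41 and CDKN2B 5.21 in resistant tumour 8. CDKN2B was 6.39 in resistant tumour 9, and LINC01503 was 5.38 in resistant tumour 11. Within the validation set the EGFR family score was -0.30 in resistant tumour 10, with lower scores in the training set, and the cholesterol and fatty acid score was -0.54 in resistant tumour 4. Resistant tumour 4 also had the highest actin 3' to 5' ratio, 12.2 against at most 4.43 in the other tumours. The correlation of its 2 arrays, 0.892, was the lowest. The remaining flagged values were in resistant tumour 12: NDP 6.40, LRP12 6.20, IRF8 4.93, REG4 4.74, ERBB3 4.57 and a classical score of -4.39.

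The difference between sensitive and resistant tumours depended on the set for 3 of 41 named genes, by the interaction test. Training exceeded validation by 5.56 for SERPINB3, 4.74 for NFE4 and 3.54 for LINC01503 (limma adjusted p = 0.0185, 0.00622 and 0.00622). With 1 sensitive tumour in the validation set, a difference between sets and a difference between tumours are confounded.

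Resistant tumour 12 lay more than 1 on the log2 scale beyond all other tumours in 566 genes, against 212 for the next tumour. Its actin 3' to 5' ratio of 2.08 was close to the median of the resistant tumours (2.07), which argues against degraded RNA, and the correlation of its 2 arrays, 0.969, was above the median of 0.955, which argues against a failed array. Of 14 abundant genes of the epithelial list, 4 were lower by less than 2 on the log2 scale (KRT18 by -0.36) while the median was -3.50 and CDH1 was at -6.45, which argues against a lower share of epithelial cells as the whole cause, since that lowers all alike. The fibroblast score was 0.65 against at most 0.41, and most markers of endothelial, myeloid and lymphoid cells lie near the floor and decide nothing. A tumour-specific programme remains a hypothesis, and a mislabelled sample was not tested.

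The 14 genes between sensitive and resistant tumours may reflect chance differences among unlike tumours: of 100 splits into 3 and 15 tumours, the real one included, 5 gave at least 14 genes, so chance cannot be excluded. The highest other split gave 486 genes and set 2 of the 3 tumours of the higher scaling target in its small group, which points to a structure of the samples. All 14 genes passed with the scaling target as a covariate, and 12 passed with the actin ratio as a covariate, which argues against either as the whole cause. Within the tumours of the lower target, 9 of the 14 passed. A difference tied to the response stays open and was not tested apart from the comparison itself.

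The 6 list shifts may come from genes of a list that move together from tumour to tumour, since 0 of the 6 passed with an estimated correlation. Of 100 splits, 41 gave at least 6 lists and the highest other split gave 13, so chance cannot be excluded. Among these splits 99 gave at least 1 list, and the median of the other splits was 5. Apart from the ribosomal list, 5 of 5 lists kept direction and threshold within the lower scaling target and with the target as covariate. Since most splits gave lists, these passes cannot decide whether the targets were a cause. The score differences of these 5 lists kept their sign in both settings and were larger within the lower target. With the covariate only that of the cholesterol and fatty acid list was smaller, at -0.48 ± 0.22 (SE) against -0.49 ± 0.21. Adjusting for the targets thus did not remove these score differences. The ribosomal list passed within the lower target (0.00460) but not with the covariate (adjusted p = 0.485), where its score difference went from -0.31 ± 0.36 (SE) to -0.11 ± 0.28, against -0.40 ± 0.32 within the lower target, so the targets stay open for it. The response of the tumours stays open as a biological difference behind single lists.

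Between resistant tumours of the 2 scaling targets, 1 of 100 splits, the real one, gave as many as 510 genes, and the highest other gave 471 with resistant tumour 12 in its small group. Another pair of tumours came close to the real count, and 38 of the other splits gave some genes, so that count cannot exclude chance. Scaling, other handling of those arrays and the 2 tumours themselves are confounded. Between training and validation resistant tumours the count of genes was 0, so all 100 splits had to give as many and the count says nothing about chance; the highest other gave 10.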

How the results depend on the processing

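The scaling as deposited, the scaling target as a covariate or left out, the actin ratio as a covariate and the merging of the 2 most similar tumours were chosen after the data were seen. The 13 named genes past the threshold kept their direction in all 457 alternative values and the threshold in 352; of 1829 values of 51 other genes, 39 crossed the threshold and 11 changed sign. The count of 14 genes became 6 and 22 with pseudocounts of 4 and 64, 5 with the mean of all probe sets and 5 with arrays numbered 1; the training count of 9 became 4 and 19 with these pseudocounts and 3 with arrays numbered 1. A filter at 9 tumours left 3 genes in all tumours and 2 in training: it removed CPE, NFE4, EPHB1, CDKN2B, LINC01503, NDP, ABCC4, TMEM273 and LRP12, while SERPINB3 in all tumours (adjusted p = 0.0516), RARRES1, training tumours alone (0.0962), and BMP4, training tumours alone (0.0595), missed the threshold. Genes whose difference depends on the set went from 6 to 1 and 35 with these pseudocounts and to 12 as deposited. With both arrays of each tumour as a block (correlation 0.629) and the replicate number as a term, 81 genes passed in all tumours, all 14 among them, 33 in training and 11 lists; arrays with the same number do not pair across tumours (median correlation -0.00521), and that fit counts arrays rather than tumours as observations. The 6 lists became 10 with no filter, 0 with an estimated correlation and 0 with fry. Without each tumour in turn, the all-tumour count ranged from 8 to 53, the training count from 5 to 67, and the lists from 5 to 8. The training counts of 67 and 32, without sensitive tumour 1 or 2, rest on 1 sensitive tumour, which is assumed to vary like the resistant ones. The EGFR pathway score difference was -0.029 with the mean of all probe sets and ranged from -0.084 to 0.13 over the leave-outs. Signs also turned for NRG1 (0.054, arrays numbered 1), BTC (-0.018, arrays numbered 2) and ERBB4 (-0.029, arrays numbered 2, and -0.022, target as a covariate). With arrays of 1 number alone, the probe set of each gene was also chosen anew. Over the leave-outs BTC ranged from -0.046 to 0.30, EGF from -0.11 to 1.24, EGFR from -0.083 to 1.19, ERBB3 from -1.08 to 0.20, ERBB4 from -0.086 to 0.55 and EPS8 from -1.24 to 0.20. The basal-like list ranged in adjusted p from 3.87e-07 to 0.301, where its direction turned. For the coordination of EGFR pathway genes the mean correlation was 0.126 with a common median and 0.0827 as deposited in resistant tumours (percentiles 18.6 and 96.4); for the coordination of EGFR pathway genes, with all 18 tumours, it was 0.147 and 0.0810 (percentiles 61.5 and 88.5). Both settings shift whole arrays, so random lists rise as well. A common median moved the median of all genes by 0.14 in training and -0.17 in validation, and scaling as deposited moved it by -0.13 and 0.50. Apart from the filter and the settings that scale whole arrays, the cause was not tested. The sensitive validation tumour ranked 1 under each alternative to the training ranking, but its difference of 1.50 became 0.555 within the scaling targets, 0.953 with 200 genes each way, 0.981 with the mean of all probe sets and 1.66 with a pseudocount of 4. Values near the floor of 4 limit small differences.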

Other observations

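The test of the neighbouring genes was chosen only after CDKN2A and CDKN2B had been seen, and CDKN2A itself was chosen after its values were seen. CDKN2A, which encodes the cell-cycle inhibitor p16 and lies next to CDKN2B, had 9.59 ± 1.93 (SD, n = 3) in sensitive and 6.43 ± 0.96 (SD, n = 15) in resistant tumours, a difference of 3.16 ± 0.65 (SE; limma adjusted p = 0.0803, or 0.0355 without resistant tumour 12). MTAP, its neighbour on the other side, differed by -0.076 ± 0.69. A change over the whole region could raise both inhibitors. The 10 measured neighbours were taken by gene order, as many on each side, and not by distance. They had a median change of 0.29 (SD 0.533), 6 of them higher and 0 past the limma threshold. The largest changes, in IFT74 (1.31), PLAA (0.93) and CAAP1 (0.80), were on the CDKN2B side. MTAP and IFNE, the first on the other side, differed by -0.076 and -0.087. The median falls short of the 2 inhibitors, but the spread leaves a small regional shift open.

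In resistant tumour 12, several transcripts of gut-like epithelium were far below those of the other resistant tumours: CEACAM5 was 5.05 against 13.6 ± 0.857 (SD) in the other resistant tumours, the adhesion gene CDH1 5.82 against 12.3 ± 0.387, and the receptor ERBB3 4.57 against 11.5 ± 0.601. Genes of the mesenchymal state were high, with vimentin, VIM, at 13.7 against 10.4 ± 0.793, the transcription factor ZEB1 at 7.94 against 5.07 ± 0.496, and fibronectin, FN1, at 12.9 against 7.09 ± 0.965. The keratin KRT18 was 13.5 against 13.9 ± 0.591. Its epithelial score was -2.85 where the other resistant tumours ranged from -0.46 to 0.80, and its mesenchymal score 1.28 where they reached at most 0.26. These genes were chosen after their values were seen.

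Marker transcripts of endothelial, myeloid and lymphoid cells were close to the floor of 4 over the 18 tumours, with median levels of 4.93, 5.07 and 5.01. PECAM1 (6.11), LAPTM5 (5.91) and CD79A (6.16) were the highest of each list. Among fibroblast markers, COL3A1 had a mean of 9.38.

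The resistant tumours most alike, 6 and 7 of the training set, had a correlation of 0.964 across genes between their means, against 0.935 for the next pair of tumours. Arrays of one correlated with arrays of the other at 0.886 to 0.952, against 0.909 and 0.925 between their own duplicates. All 4 of their arrays were nearest to an array of the other tumour, and 0 array pairs in the series were identical. The cause was not tested. The training fit was not run with these tumours counted as 1, so its counts treat them as independent.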
